A study of Mus musculus with 39 samples.

How the data were processed

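Expression was measured on 24 arrays of total RNA and promoter binding in 15 chromatin immunoprecipitation (ChIP) samples, which makes 39 samples, all from mouse. Per the labels, RNA was extracted with Trizol and RNeasy, labelled with biotin and hybridised by the standard Affymetrix protocol. Per the labels, the immunoprecipitated DNA carried Cy5 and input DNA without immunoprecipitation carried Cy3. The series text says that each cell type was measured in duplicates of a pair of lines and that ChIP was done in biological duplicates. Which line each ChIP hybridisation came from is not given in the sources used here.

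The expression table, deposited by the authors, holds linear intensity values that are quantile normalised, as seen from the values themselves. The software and the summary method are not given in the sources used here. The number of values repeated within an array divided the table into 15 arrays with 21937 to 23357 repeats (ES, iPS, MEF and piPS) and 9 arrays with 45 to 82 (OCK, induced and uninduced MEF, 1A2 colonies and sorted 1A2 cells). The arrays were thus processed in at least 2 ways, and comparisons across them carry that difference. Each ChIP hybridisation was deposited as a file per slide, with 2 slides per hybridisation. Per the file headers, they hold foreground and background intensity per channel, and intensity values of both channels after the authors' background subtraction and normalisation. The log2 ratio of these normalised values equals the ratio given in the files. Per the file headers, 2 further columns of another unit (other), values of 0 or 1, mark spots that the authors excluded and probes in regions that they called bound. The genome build of the probe positions is not given in the sources used here. A value table of each ChIP platform was not used here, since its numbering could not be matched to the probes.

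Expression values were taken as log2(value + 16). Of 45101 probe sets 64 controls were left out. Probe sets above the 40th percentile of their array in at least 2 of the 24 arrays were kept, which left 36826. Since probe sets were not tied to genes here, each was tested on its own. limma fitted the ES, iPS, piPS, MEF and OCK groups together over 17 arrays from 10 lines, with line as a random block (correlation 0.1184) and a prior of 2.004 degrees of freedom. A probe set was called with an adjusted p under 0.05 (Benjamini-Hochberg, per contrast) and at least a 2-fold difference. Tests are two-sided. There were 8 contrasts. Overlaps of contrasts that share a control group were compared with the overlap if independent, with 20 simulations without change, and with calls made on separate control arrays. Position is the median over probe sets of the array minus the MEF mean, divided by the ES mean minus the MEF mean, with ratios limited to -1 and 2 in an alternative. Positions of lines were compared by exact permutation. Single-array conditions were given as log2 differences without a test, against the uninduced MEF array or the mean of the 1A2 arrays. The median of each class of probe sets was set against 10000 random lists matched on mean expression. Fold counts there cover probe sets above the median in the brighter sample.

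For ChIP, excluded spots and controls were left out, and log2 ratios were centred on the median of each slide. Of 474380 data probes 450722 lay in 16819 promoters, with a median of 27 probes each. Promoters took their gene from the accession (16436), the symbol (207) or a synonym (119), and 57 kept the name in the file. Annotation that is divergent or shares probes covers 3126 promoters, so genes such as Alg3 and Eef1akmt4, or Ifitm1 and Ifitm2, share a value. The promoter score is the highest mean of 3 neighbouring probes within 1000 bp, on the mean over the hybridisations of a sample. Bound promoters scored at or above the lowest threshold at which mirrored scores (minus the lowest mean of 3 probes) that high numbered at most 5.0% of the real ones. Promoters bound in ES cells were compared between iPS and piPS cells by exact McNemar tests, for 4 factors. Their promoters are not independent replicates, so these tests and the Fisher tests over promoters compare these samples only. p-values were written no smaller than 1e-300. Scores of single hybridisations were tested per factor with limma over ES, iPS and piPS cells (adjusted p under 0.05 per contrast). A hybridisation was called noisy with over 2.0% of its spots excluded or a log2 ratio SD over 1, which 3 of 33 were. The hybridisations fell into 13 scan batches, and comparisons were repeated within the 1 batch that held iPS and piPS cells of a factor and with batch as a block. The area under the curve gives how well a hybridisation ranked the promoters bound in ES cells.

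The gene lists, 18 in number, and the rule for named genes were fixed with the other choices before the data were examined. The lists cover reprogramming factors, pluripotency, fibroblast, mesenchymal transition, epithelial, cell cycle, ribosome biogenesis and growth, glycolysis, developmental regulators, primitive endoderm and trophoblast, neural, blood and endothelial, chromatin and DNA methylation, imprinted, interferon response, p53 and senescence, germline and sex chromosome genes. List tests used Fisher's exact test, exact McNemar and sign tests and 10000 random lists, each adjusted over all lists and factors. The rule names the promoters of Pou5f1, Sox2, Nanog, Klf4 and Myc and of the pluripotency list, the 5 highest-scoring promoters per factor in ES cells and the 5 with the largest ES minus piPS difference. It names up to 3 called members per list, and the 5 largest rises and 5 largest falls per expression contrast, of which the text gives fewer. The Nanog promoter was not analysed here. The series has no further columns to map, with 0 left unmapped.

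The methods were tested on simulated data. In simulated expression values with line correlation, between 55 and 75 percent of probe sets changed 4-fold were called, between 15 and 24.1 percent of those changed 2-fold, and 12 to 30 unchanged probe sets of 36830. In simulated promoters the share of false calls was 3.77% to 5.80%. In simulated scores limma recovered changes of 1 and 2 in 42.5% and 79% of promoters for Oct4, 91.5% and 99.5% for Sox2, 70.5% and 94% for Klf4, and 0% and 16.5% for c-Myc. The test thus had little power for c-Myc.

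Alternatives covered the pseudocount, the low-value filter, quantile normalisation, no minimum fold, averaging per line, other thresholds and window sizes, normexp background correction (limma, offset 50) from the foreground and background intensities, and leaving out each replicate and line. Chosen after the data had been seen were the runs with hybridisations scaled to an equal SD, without noisy hybridisations, within scan batches, with batch as a block, with the authors' bound regions, and with 1 ES array left out as an end of position. Not run were set tests on expression, a mean over the probe sets of a gene, the check of sex-linked genes with its list of sex chromosome genes, the relation of binding to expression, and the platform value tables as an alternative. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.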

Results

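Gene expression and promoter binding were measured in mouse cells before, during and after reprogramming to pluripotency. Mouse embryonic fibroblasts (MEF) were the starting cells, and embryonic stem (ES) cells the target. Induced pluripotent stem (iPS) lines had been fully reprogrammed with Oct4, Sox2, Klf4 and c-Myc. Partially reprogrammed (piPS) lines had received the factors and had not reached the pluripotent state. Expression was measured on 24 arrays. They covered 4 ES arrays (lines v6.5 and E14, 2 each), 4 iPS arrays (lines 1D4 and 2D4, 2 each), 3 piPS arrays (2 of line 1A2 and 1 of line 1B3) and 4 MEF arrays (2 male, 2 female). There were 2 arrays of OCK lines, which are clones from cells infected with Oct4, c-Myc and Klf4 but not Sox2. The other arrays had 1 per condition: MEF with Oct4, Sox2, c-Myc or Klf4 induced alone, uninduced MEF, 1A2 colonies, and 1A2 cells sorted for GFP.

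Binding was measured by chromatin immunoprecipitation on promoter arrays (ChIP) in 15 samples with 33 hybridisations. Oct4, Sox2, Klf4 and c-Myc were measured in ES, iPS and piPS cells with 2 to 4 hybridisations each. Nanog was measured in ES cells with 2 hybridisations. The histone marks H3K4me3, found at active promoters, and H3K27me3, found at promoters repressed by Polycomb, were measured in piPS cells with 1 hybridisation each. The number of arrays limits the precision of every value. The labels do not say which hybridisations came from separate cultures, so p-values from limma measure the spread between these samples, and those computed over promoters or lists contain no spread between samples. A promoter score is the highest mean log2 ratio of immunoprecipitated over input DNA across 3 neighbouring probes. Scores are given as mean ± SD over hybridisations. The genome build of the coordinates is not given in the sources used here.

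The first question was whether Oct4 occupied in iPS and piPS cells the promoters that it occupied in ES cells. Oct4 bound 2105 promoters in ES cells, 4066 in iPS cells and 2 in piPS cells. At Dppa5a, a gene expressed in pluripotent cells, the Oct4 score was 2.68 ± 0.19 (SD, n = 2) in ES cells, 2.86 ± 0.19 (n = 2) in iPS cells and 0.28 ± 0.03 (n = 2) in piPS cells (chromosome 9, 78154301 to 78154662 in ES). At Mycn, a Myc family oncogene, the scores were 3.36 ± 0.05, 3.84 ± 0.25 and 1.38 ± 0.03 (chromosome 12, 12969126 to 12969450). At Sox2, they were 2.07 ± 0.13, 2.73 ± 0.16 and 0.68 ± 0.24 (chromosome 3, 34837831 to 34838164 in ES). Pou5f1, which encodes Oct4 itself, had Oct4 scores of 2.36 ± 0.57, 2.48 ± 0.13 and 1.20 ± 0.67 (chromosome 17, 35111895 to 35112301 in ES), and its difference between piPS and iPS did not pass the test. Of 35 promoters of pluripotency genes, 29 were bound by Oct4 in ES cells. Of these, 28 were also bound in iPS cells and 0 in piPS cells (adjusted exact McNemar p = 5.07e-07), where 0.0963% of the other ES-bound promoters were bound. With 2 promoters bound in piPS cells in all, that test could hardly have come out otherwise and says nothing particular to this list. The threshold was 2.38 in piPS, 0.707 in ES and 0.658 in iPS cells. The mean piPS scores of Mycn and Pou5f1 lay above the ES threshold but counted as unbound.

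Tested per promoter with limma, Oct4 scores of 23 promoters fell and 0 rose in piPS against iPS cells, among 16495 tested. The fall was 2.58 log2 units at Dppa5a (log2 difference -2.58, SE 0.169, adjusted p = 0.0411), with -2.46 at Mycn, -2.56 at the amino acid transporter gene Slc7a3, -2.05 at Sox2 and -1.99 at Trp53, the gene of the p53 tumour suppressor. Of the pluripotency promoters, 2 of 35 fell, and 22 fell when adjusted over the list alone. Between iPS and ES cells limma called 0 promoters for Oct4, with 322 at an unadjusted p under 0.05. Between piPS and ES cells it called 0, with 769 at an unadjusted p under 0.05. These counts depended on the scaling. Between piPS and ES cells 265 were lower and 0 higher with each hybridisation scaled to the same SD. With normexp 302 were lower and 14 higher, and 98 were higher between iPS and ES cells. Without piPS replicate 1, which leaves only the noisy piPS hybridisation, the direction between piPS and ES cells turned. More promoters were then higher than lower.

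Over all promoters bound by Oct4 in ES cells, 88.3% were also bound in iPS and 0.0950% in piPS cells (exact McNemar p = 1e-300, the smallest written). The piPS share followed the threshold. It was 18.3% (iPS 86.3%) at a score of at least 1 in every cell type, and 41.2% (iPS 69.8%) by the regions that the authors called bound in any hybridisation. Among the 1000 highest-scoring Oct4 promoters of each cell type, where the threshold plays no part, ES cells shared 679 with iPS and 273 with piPS cells. Within the 1 scan batch that held both cell types, the 1000 highest shared 679 and 355. By threshold the shares there were 88.3% and 0.285%, from a piPS hybridisation with 6 bound promoters in all. With scan batch as a random block limma called 36 higher and 742 lower promoters in piPS against iPS. That block can lean on the 1 piPS hybridisation that shares a batch with iPS, so its counts are no separate support for a fall. A fixed block absorbs piPS replicate 2, which is alone in its batch. It therefore compares a single piPS hybridisation with iPS, and its counts are not used here. One of the 2 piPS hybridisations was noisy, with 5.44% of its spots excluded. Without it 248 promoters were called, and without the other piPS hybridisation 2746 were called higher and 505 lower. Leaving out any single ES or iPS hybridisation for Oct4 left 0 calls, and ES cells had 467 bound promoters without ES replicate 1.

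For Sox2, the bound promoters numbered 2015 in ES, 2241 in iPS and 115 in piPS cells. Dppa5a had Sox2 scores of 1.37 ± 0.30 (SD, n = 2) in ES, 2.00 ± 0.08 (n = 4) in iPS and 0.38 ± 0.01 (n = 2) in piPS cells. Mycn had 1.76 ± 0.09, 2.67 ± 0.36 and 0.85 ± 0.38. Rif1, which acts in telomere biology and replication timing, was among the promoters with the highest Sox2 scores in ES cells and was bound in all of the cell types, at 2.47 ± 0.55, 2.44 ± 0.50 and 1.87 ± 0.27 (chromosome 2, 51894003 to 51894501 in ES). Of 24 pluripotency promoters bound by Sox2 in ES cells, 23 were bound in iPS and 4 in piPS cells (adjusted exact McNemar p = 0.00013). The piPS share of 16.7%, against 3.72% of other promoters, was not called different (adjusted Fisher p = 0.277). Limma called 149 promoters lower and 11 higher in piPS against iPS cells. Dppa5a fell by 1.61 (log2 difference -1.61, SE 0.127, adjusted p = 0.000356), Mycn by a log2 difference of -1.81 and Pou5f1 of -0.75. Among the pluripotency promoters 9 of 35 fell, and 23 when adjusted over the list alone (adjusted Fisher p = 1.83e-09). Among 26 promoters of chromatin and DNA methylation genes 3 fell, and 5 when adjusted over the list alone (adjusted Fisher p = 0.0328). Both Fisher tests compare with all other tested promoters, bound or not. They do not tell a list effect from a high score in iPS cells. The promoter of Myc, which encodes c-Myc, went the other way. Its Sox2 score rose in piPS against iPS cells (log2 difference 1.26, SE 0.223, adjusted p = 0.0187) and against ES cells (1.53, SE 0.258, adjusted p = 0.0499).

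Of the promoters bound by Sox2 in ES cells, 56.3% were bound in iPS and 3.87% in piPS cells (exact McNemar p = 1e-300, the smallest written). The iPS profile averaged 4 hybridisations and the piPS profile 2, so the shares rest on unequal numbers. The iPS share was 34.7% without iPS replicate 4 and 24.3% from iPS replicates 1 and 3 alone. Taken singly, the iPS hybridisations other than replicate 4 bound 93 to 177 promoters, and piPS replicate 2 bound 1505. The piPS share was 37.9% without piPS replicate 1, 20.3% (iPS 40.8%) with normexp and 43.6% (iPS 66.1%) by the regions that the authors called bound in any hybridisation. The 1000 highest-scoring promoters of ES cells shared 524 with iPS and 327 with piPS cells. The 1 scan batch with both cell types held only piPS replicate 1, which had 1 bound promoter in all, so that comparison within the batch says nothing about the shares. With scan batch as a random block limma called 12 Sox2 promoters higher and 170 lower in piPS against iPS. A fixed block again leaves piPS replicate 1 alone against iPS, so its counts are not used here. The Sox2 counts rested on single hybridisations. They were 3872 without ES replicate 1, 243 without ES replicate 2, 1003 without iPS replicate 4, 1505 without piPS replicate 1 and 1 without piPS replicate 2. The 160 promoters called between piPS and iPS became 334 without either ES replicate, 100 and 103 without iPS replicates 1 and 2, and 20 and 26 without piPS replicates 1 and 2. Between iPS and ES cells limma called 5 Sox2 promoters higher and 0 lower, with 1413 at an unadjusted p under 0.05, and between piPS and ES cells 7 higher and 15 lower. Without ES replicate 1 they became 22 higher and 468 lower between iPS and ES cells, which turns the direction, and 13 higher and 869 lower between piPS and ES cells. Every other hybridisation left out gave fewer calls between piPS and ES cells, 5 higher and 7 lower without ES replicate 2, 4 to 11 in all without an iPS replicate, and 4 and 2 higher and 0 lower without piPS replicates 1 and 2. They were 6 and 24 with normexp, 3 and 61 with each hybridisation scaled to the same SD, and 5 and 3 with scan batch as a random block. Between iPS and ES cells the 5 became 16 higher and 6 lower without ES replicate 2, 0 without iPS replicate 1 or either piPS replicate, and 0 higher and 3 lower with the same SD.

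Klf4 bound 6946 promoters in ES, 6372 in iPS and 4289 in piPS cells. At some of its strongest ES targets the piPS score lay within the spread of the ES score. S100a14, a gene of the S100 calcium-binding family, had scores of 2.77 ± 0.49 (SD, n = 3) in ES, 3.15 ± 0.28 (n = 2) in iPS and 2.65 ± 0.31 (n = 2) in piPS cells (chromosome 3, 90611462 to 90611812). At some pluripotency genes the piPS score was lower. Zfp42, also called Rex1 and a marker of naive pluripotency, had 2.12 ± 0.39, 2.29 ± 0.02 and 0.57 ± 0.22 (chromosome 8, 44805799 to 44806391 in ES). Dnmt3l, a cofactor of the de novo DNA methyltransferases, had 1.86 ± 0.16, 2.43 ± 0.23 and 0.33 ± 0.06 (chromosome 10, 77452207 to 77452558). Of the 32 pluripotency promoters bound by Klf4 in ES cells, 31 were bound in iPS and 15 in piPS cells (adjusted exact McNemar p = 0.000692). The piPS share of 46.9% was not called different from the 53.1% of other promoters (adjusted Fisher p = 1).

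Limma called 872 promoters with a lower and 33 with a higher Klf4 score in piPS than in iPS cells. With each hybridisation scaled to the same SD only 28 were lower and 2 higher, and the list tests below were not repeated on that scale. Dnmt3l fell by 2.10 (log2 difference -2.10, SE 0.168, adjusted p = 0.00185) and Zfp42 by 1.73 (-1.73, SE 0.231, adjusted p = 0.00741). Pou5f1 (-1.14), Sox2 (-1.02) and Klf4 (-0.78) fell as well, which are 3 of the 4 reprogramming factor genes. So did Tcl1, a coactivator of Akt, at -1.82, the Nodal pathway genes Lefty2, Lefty1 and Nodal at -1.57, -1.33 and -1.27, and the Klf family genes Klf5 and Klf2 at -0.86 and -0.68. Of the pluripotency promoters 20 of 35 fell, and 30 when adjusted over the list alone (adjusted Fisher p = 7.19e-15). Of 22 epithelial promoters 6 fell, and 13 over the list alone (adjusted Fisher p = 0.0196). Of 34 promoters of developmental regulators 9 fell, and 19 over the list alone (adjusted Fisher p = 0.00248). Of 25 primitive endoderm and trophoblast promoters 7 fell, and 12 over the list alone (adjusted Fisher p = 0.00949). Of 28 cell cycle and 26 ribosome biogenesis and growth promoters, 1 each fell, and 1 each over the list alone. The Fisher tests set each list against all other tested promoters, bound or not. Median percentile ranks of the Klf4 score in iPS cells were 95.6 for pluripotency, 66.2 for cell cycle and 59.3 for ribosome biogenesis and growth promoters. A low score has little room to fall, so the tests do not tell a list effect from a high score in iPS cells.

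Among all promoters bound by Klf4 in ES cells, 80.0% were bound in iPS and 53.1% in piPS cells (exact McNemar p = 1e-300, the smallest written). The piPS share depended on the threshold and the background correction, with 10.2% (iPS 75.9%) for mirrored scores at 1 percent and 20.1% (iPS 83.5%) with normexp. It also rested on 1 hybridisation, with 7.30% without piPS replicate 2 and 43.6% without piPS replicate 1. The gap at 1 percent, 65.8 points, was wider than that of Sox2 (58.1). The 1000 highest-scoring promoters shared 699 with iPS and 511 with piPS cells, and 699 and 363 within 1 scan batch, which held a single piPS hybridisation. With scan batch as a random block 940 Klf4 promoters were higher and 4311 lower in piPS than in iPS cells. That block can lean on piPS replicate 1, the only piPS hybridisation in a batch with iPS, so its counts are no separate support for a fall. A fixed block absorbs piPS replicate 2, which is alone in its batch. It therefore compares a single piPS hybridisation with iPS, and its counts are not used here. Without piPS replicate 2 the piPS count was 549, and the 905 calls between piPS and iPS became 9 without piPS replicate 1, 38 without iPS replicate 1 and 17 without iPS replicate 2. Between iPS and ES cells Klf4 had 8 promoters higher and 0 lower in limma, with 3612 at an unadjusted p under 0.05. The 8 became 0 with scan batch as a random block, with each hybridisation scaled to the same SD, without ES replicate 1 and without either piPS replicate, and 1 and 5 without iPS replicates 1 and 2. They rose to 239 with 5 probes, 32 with normexp, 16 without ES replicate 2, and 20 higher and 3 lower without ES replicate 3. Between piPS and ES cells 6 were higher and 48 lower, with Zfp42 (-1.56), Dnmt3l (-1.53), Fbxo15 (-1.25) and Dppa4 (-1.13) among the pluripotency genes that fell. Without piPS replicate 1 or 2 those calls between piPS and ES became 0, and without either iPS replicate 0 higher and 3 lower. Normexp gave 1202 higher and 1260 lower, almost even, while 5 probes gave 14 and 72, the same SD 16 and 142, and scan batch as a random block 0 and 13.

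c-Myc in piPS cells bound more of its ES promoters at genes of ribosome biogenesis and growth than elsewhere, with both piPS hybridisations together. It bound 6368 promoters in ES, 4225 in iPS and 1666 in piPS cells. The strongest was Eif1a, a translation initiation factor gene, at 3.67 ± 0.31 (SD, n = 3) in ES, 3.78 ± 0.94 (n = 3) in iPS and 3.84 ± 0.52 (n = 2) in piPS cells (chromosome 18, 46723137 to 46723599). Nop58, a core protein of the small nucleolar ribonucleoproteins that modify ribosomal RNA, had 3.02 ± 0.36, 3.88 ± 1.54 and 3.53 ± 1.08 (chromosome 1, 59629643 to 59630048). Of 26 ribosome biogenesis and growth promoters, c-Myc bound 25 in ES, 21 in iPS and 18 in piPS cells. Of those bound in ES cells 72.0% were bound in piPS cells, against 24.2% of other promoters (adjusted Fisher p = 4.74e-05). For glycolysis promoters the shares were 66.7% and 24.3% (adjusted Fisher p = 0.0219). These tests were not matched on the c-Myc score in ES cells, where ribosome biogenesis and growth promoters had a median percentile of 96.1. The threshold was 0.472 in ES and 1.33 in piPS cells, so strong promoters pass it more readily whatever their list. A list effect was not told apart from the score in ES cells. Of 28 cell cycle promoters all were bound by c-Myc in ES cells, 17 in iPS and 4 in piPS cells (adjusted exact McNemar p = 0.00277). The piPS share of 14.3%, against 24.5% of other promoters, was not called different (adjusted Fisher p = 0.996). Of 24 pluripotency promoters bound in ES cells, 18 were bound in iPS and 4 in piPS cells (adjusted exact McNemar p = 0.00166), again not called different from other promoters in the piPS share (16.7% and 24.5%, adjusted Fisher p = 1).

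The share of ES-bound c-Myc promoters was 51.2% in iPS and 24.4% in piPS cells (exact McNemar p = 8.60e-293), and within 1 scan batch 47.0% and 30.2% (exact McNemar p = 3.59e-115). At a score of at least 1 they were 86.9% and 81.8%. Among the 1000 highest-scoring promoters the order turned, with 528 shared between ES and iPS and 592 between ES and piPS cells. Within the scan batch they were 463 and 598, with the noisy iPS replicate 2 included and the noisy piPS replicate 2 left out. One c-Myc hybridisation of iPS and 1 of piPS cells were noisy. Without both, the shares were 76.0% and 30.2%, and the 1000 highest shared 716 and 598. Limma called 0 c-Myc promoters between piPS and iPS, iPS and ES, and piPS and ES. In that order 90, 96 and 111 had an unadjusted p under 0.05, and these counts were unstable. Without iPS replicate 3 they were 2006, 5056 and 252. Without the noisy iPS replicate 2 they were 432, 45 and 1238. With scan batch as a random block they were 79, 3533 and 359, again with 0 called. With each hybridisation scaled to the same SD, 3 were higher and 191 lower in piPS than in ES cells, and with normexp 1 was lower. Without piPS replicate 1 the piPS count was 159 and the piPS share 2.36%, and the comparisons with gene lists were not repeated without it.

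**Figure D1:**
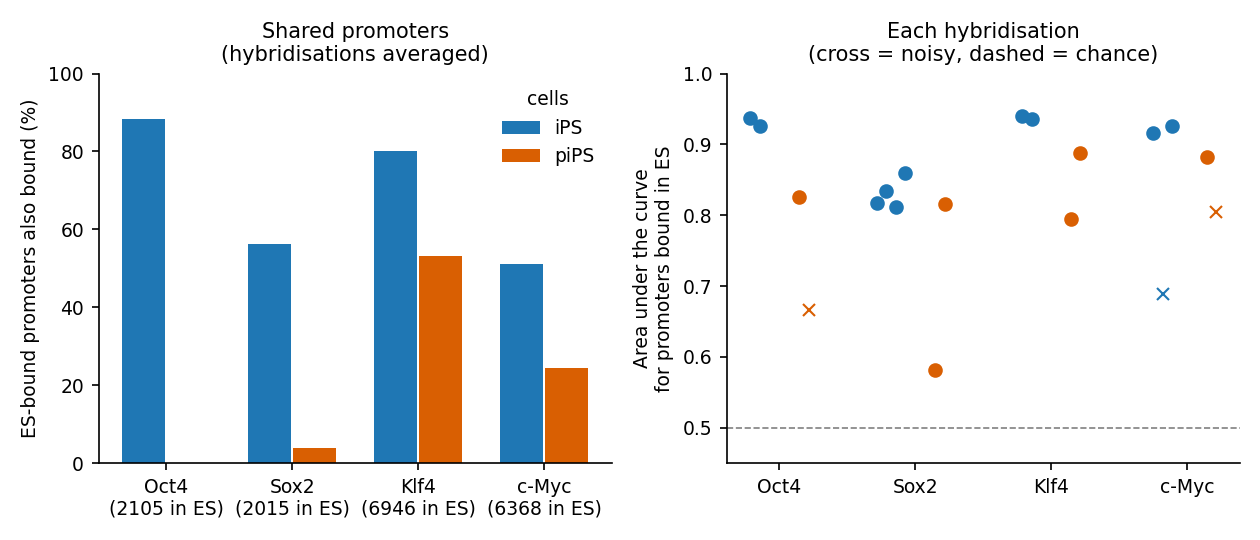
Share of the promoters bound in ES cells (percent, vertical axis) that were also bound in iPS and in piPS cells, for Oct4, Sox2, Klf4 and c-Myc. With thresholds from mirrored scores, the shares in iPS and piPS cells were 88.3% and 0.0950% for Oct4, 80.0% and 53.1% for Klf4, and 51.2% and 24.4% for c-Myc. The size and order of the gaps depended on the threshold. The right panel gives the area under the curve with which each hybridisation ranked the promoters bound in ES cells, with crosses for noisy hybridisations and a dashed line at 0.5, the value without ranking.

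Promoters carrying all 4 factors numbered 873 in ES, 1005 in iPS and 2 in piPS cells. The piPS count could not be higher, since Oct4 passed its threshold there at 2 promoters in all. The other gene lists are described by the median percentile rank of their promoters' scores. Pluripotency promoters had median Oct4 percentiles of 99.1 in ES, 98.9 in iPS and 83.9 in piPS cells (adjusted exact sign p = 0.0182 for iPS against piPS), and median Klf4 percentiles of 94.5, 95.6 and 67.8 (adjusted exact sign p = 0.000236). Lower Oct4 ranks in piPS were not particular to this list. They also held for developmental regulators (adjusted exact sign p = 0.0222) and chromatin and DNA methylation genes (adjusted exact sign p = 0.0212), while fibroblast promoters divided evenly (18 of 36). The ranks were not recomputed without the noisy hybridisations. Developmental regulators were bound by Oct4 at 9 promoters in ES, 21 in iPS and 0 in piPS cells, where Oct4 bound 2 promoters in all. They were bound by Klf4 at 29, 28 and 11. For fibroblast genes, Klf4 bound 18 of 36 promoters in ES cells, of which 16 were bound in iPS and 13 in piPS cells (adjusted exact McNemar p = 0.447). For mesenchymal transition genes, Klf4 bound 13 of 14 in ES cells and 10 each in iPS and piPS cells. Ribosome biogenesis and growth promoters had median c-Myc percentiles of 96.1, 90.8 and 97.5.

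**Figure D2:**
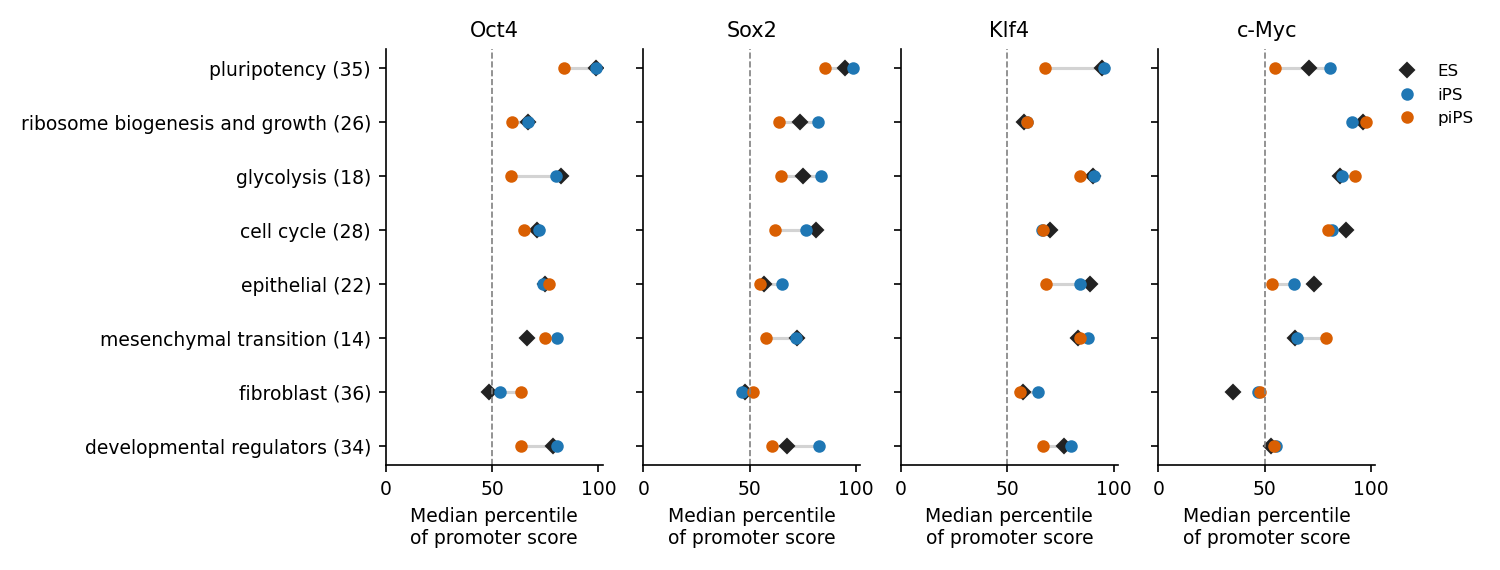
Median percentile rank of the promoter score (0 to 100, horizontal axis) of fixed gene lists, with the number of promoters in parentheses, for each factor in ES, iPS and piPS cells. Pluripotency promoters ranked lower in piPS than in iPS cells for all 4 factors, and ribosome biogenesis and growth promoters kept a median c-Myc percentile above 90 in each cell type (96.1, 90.8 and 97.5). Developmental regulators also ranked lower in piPS than in iPS cells for Oct4 and Klf4. All hybridisations are included, also the noisy ones.

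The histone marks in piPS cells differed between gene groups. H3K4me3 passed the threshold at 5104 promoters, a number that ranged from 1 with normexp and 1506 with mirrored scores at 1 percent to 8601 at a score of at least 1. It marked 22 of 26 ribosome biogenesis and growth promoters (adjusted Fisher p = 3.18e-07) and 22 of 28 cell cycle promoters (adjusted Fisher p = 3.47e-06), against 30.3% of other promoters. It marked 9 of 35 pluripotency promoters, 7 of 34 developmental regulators and 5 of 36 fibroblast promoters, and these lists did not differ from other promoters. Promoters of developmental regulators had the highest H3K27me3 ranks, with a median percentile of 97.2 (adjusted permutation p over random lists = 0.00146), followed by primitive endoderm and trophoblast genes at 92.7 and neural genes at 91.7. Fibroblast genes were at 83.7 and pluripotency genes at 71.9 (adjusted permutation p over random lists = 0.0185). Ribosome biogenesis and growth genes were at 23.9. Foxd3, a forkhead factor of early development and pluripotency, had an H3K27me3 score of 2.51 and an H3K4me3 score of 1.66. The Sox2 promoter had 2.00 and 2.44. At Pou5f1 both were low, with 0.84 for H3K27me3 and 0.68 for H3K4me3. Promoters bound by c-Myc in piPS cells carried H3K4me3 in 77.6% of cases against 25.2% of others (Fisher p = 1e-300, the smallest written), and those bound by Klf4 in 59.3% against 20.4% (Fisher p = 1e-300, the smallest written). With normexp, where 1 promoter carried the mark, both differences reversed. Promoters that Klf4 bound in ES but not piPS cells carried it in 35.3% of cases. H3K27me3 itself passed the threshold at 40 promoters, a number that depended on the threshold, with 4410 at a score of at least 1 and 440 with 5 probes per window. There was 1 hybridisation per mark and no other cell type, so these values carry no replicate error.

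The expression arrays asked how far each cell type lay between MEF and ES cells. Probe sets were not tied to genes here and are given by identifier. Between ES cells and MEF limma called 6061 probe sets higher and 5665 lower in ES, among 36826. Probe set 1450989_at rose most, from 4.58 ± 0.35 (SD, n = 4) on the log2 scale in MEF to 16.13 ± 0.17 (n = 4) in ES cells (SE of the difference 0.374, adjusted p = 1.30e-10). Low values such as this one in MEF lie near the floor set by the 16 added before the log. The size and rank of the largest differences depend on it. Probe set 1417945_at rose by 10.60 (SE 0.207, adjusted p = 9.30e-13). Probe set 1450625_at fell by 7.45 (SE 0.578, adjusted p = 2.52e-07).

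iPS lines differed from ES cells at 739 probe sets that were higher and 982 that were lower in iPS. Probe set 1449962_at was 13.51 ± 0.30 (SD, n = 4) in iPS and 5.69 ± 1.00 (n = 4) in ES cells (adjusted p = 1.31e-06). Probe set 1438239_at was 5.94 ± 1.00 in iPS and 13.69 ± 0.50 in ES cells (adjusted p = 1.54e-05). These counts depended on single lines. They were 257 higher and 229 lower without line 1D4, 429 and 611 without 2D4, and 475 and 311 without E14. Single ES arrays moved the lower count to 654 (without ES replicate 2) and 612 (without ES replicate 3), and with values averaged per line 147 were higher and 128 lower.

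piPS lines had moved part of the way. Against MEF, 3933 probe sets were higher and 3931 lower in piPS, and against ES cells 3677 were higher and 3822 lower. Of the 6061 probe sets higher in ES cells than in MEF, 2165 (35.7%) rose in piPS against MEF, and 2470 (40.8%) were lower in piPS than in ES cells. Of the 5665 higher in MEF, 2599 (45.9%) fell in piPS, and 1903 (33.6%) stayed higher than in ES cells. Probe set 1417945_at rose in piPS by 11.06 (SE 0.221, adjusted p = 1.29e-12), to a mean of 16.01 in piPS against 15.55 in ES cells. Since probe sets were not tied to genes, those that measure the factors given to piPS and OCK cells were not set apart. A rise in these cells can therefore include signal from the introduced factors. Probe set 1437752_at was 4.57 ± 0.28 (SD, n = 3) in piPS against 14.67 ± 0.08 (n = 4) in ES cells (adjusted p = 2.57e-08). Beyond either end, 1207 probe sets were above and 936 below both MEF and ES cells in piPS. Against iPS cells directly, 3146 were higher and 3053 lower in piPS. Probe set 1429388_at was 5.44 ± 0.67 (n = 3) in piPS and 15.45 ± 0.11 (n = 4) in iPS cells (adjusted p = 9.43e-09), and 1460000_at was 14.97 ± 0.12 and 6.71 ± 0.26 (adjusted p = 1.73e-07). Without line 1A2 the single 1B3 array, assumed to vary like the other groups, gave 1714 higher and 2276 lower against iPS and 2357 and 2827 against ES cells.

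ES and piPS cells were both compared with the same MEF arrays, which by itself makes the differences resemble each other. Probe sets higher in both numbered 2165, against 647 if the calls were independent. In 20 simulations without change 0 were called in both. Data without change and without lines can give little else, so that count is no yardstick for the overlap. The differences had a correlation across probe sets, which are not independent, of 0.610 (simulated 0.461) and a covariance of 1.13 (simulated 0.0856). With separate MEF arrays for each comparison, 1650 were higher in both against 503 if independent. For probe sets lower in both the counts were 2599 against 605, and 1944 against 417 with separate MEF arrays.

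OCK lines, made without Sox2, had also moved part of the way. Against MEF 3840 probe sets were higher and 4175 lower in OCK, against ES cells 5210 and 5772, and against piPS 2500 and 3148. Of the probe sets higher in ES cells 1420 (23.4%) rose in OCK and 3334 (55.0%) were lower in OCK than in ES cells. Of those higher in MEF, 2082 (36.8%) fell and 2466 (43.5%) stayed higher than in ES cells. Probe set 1418362_at was 5.15 ± 0.28 (SD, n = 2) in OCK and 15.31 ± 0.38 (n = 4) in ES cells (adjusted p = 1.67e-09), and 1438729_at was 12.96 ± 0.93 (n = 2) in OCK and 4.44 ± 0.10 (n = 3) in piPS (adjusted p = 2.27e-07). Above both MEF and ES cells were 1928 probe sets in OCK, of which 599 were also above both in piPS. OCK and piPS shared 1781 probe sets higher than MEF (410 if independent, and 677 against 144 with separate MEF arrays), with a correlation of 0.640 (simulated 0.379) and a covariance of 1.08 (simulated 0.0864). ES and OCK shared 1420 (632 if independent, and 525 against 242 with separate MEF arrays), with a covariance of 0.803 (simulated 0.0853) and a correlation of 0.425, close to the simulated 0.407.

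The OCK, induced MEF and 1A2-derived arrays differed from the other 15 arrays in how their values had been made. They held 45 to 82 repeated values each, and the others 21937 to 23357. The OCK comparisons carry that difference. Against the 1 uninduced MEF array made in the same way, 93.3% of the probe sets called higher and 88.5% of those called lower in OCK against MEF had the same direction. At least 2-fold in that direction were 67.3% and 62.5%, and 34 and 94 probe sets were 2-fold in the opposite one. Against the 1A2 colonies and sorted cells, also made in the same way, 93.0% and 87.4% of the calls of OCK against piPS had the same direction, 51.7% and 39.1% at least 2-fold, with 16 and 33 opposite at 2-fold. The same OCK arrays enter both sides of these checks. ES cells had no array made in that way. Without line 1A2, OCK against piPS gave 1492 higher and 1912 lower.

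Position summarised these distances, with 0 at the MEF mean and 1 at the ES mean, over probe sets higher in ES cells and those higher in MEF. iPS arrays lay at 0.882 ± 0.0171 (SD, n = 4) and 0.880 ± 0.0377, piPS at 0.497 ± 0.00804 (n = 3) and 0.568 ± 0.0159, and OCK at 0.267 ± 0.00327 (n = 2) and 0.437 ± 0.0162. Within lines, the position of the probe sets higher in MEF exceeded that of the probe sets higher in ES by 0.0750 in piPS (2 lines) and 0.169 in OCK (2 lines), both with exact p = 0.5, the smallest that 2 lines allow. Between lines, piPS minus iPS was -0.385 for the probe sets higher in ES and -0.307 for those higher in MEF, and OCK minus piPS was -0.231 and -0.136, each with exact permutation p = 0.333, the smallest that 2 lines against 2 allow.

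**Figure D3:**
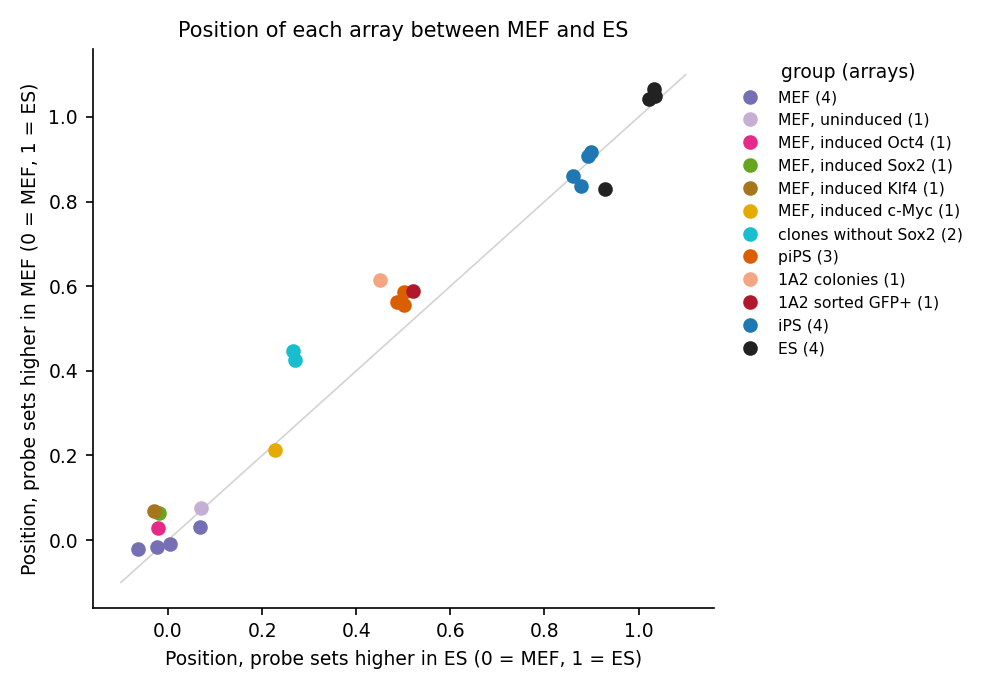
Position of each expression array between the MEF mean (0) and the ES mean (1), for probe sets higher in ES cells and probe sets higher in MEF, 1 point per array. iPS arrays lie near 0.88, piPS arrays near 0.50 and 0.57, OCK arrays near 0.27 and 0.44, and the MEF array with c-Myc induced (0.227 and 0.214) lies nearer to ES cells than the uninduced one (0.0694 and 0.0749).

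Induction of single factors in MEF asked what each factor does alone. With 1 array per factor and 1 shared uninduced array, no test was made. With c-Myc, both classes of probe sets lay towards ES cells, with a median log2 difference of 0.32 for the probe sets higher in ES and -0.29 for those higher in MEF, each beyond all of 10000 random lists. Random lists carry no error between arrays, and replicate arrays of v6.5 differed by medians of -0.19 and 0.42 for the same classes and those of male MEF by -0.12 and 0.08. Oct4 gave -0.16 and 0.11, Sox2 -0.17 and 0.03, and Klf4 -0.15 and 0.02. These were also each beyond all of the random lists, lower for the probe sets higher in ES and higher for those higher in MEF. All are differences from the 1 uninduced array, whose positions were 0.0694 and 0.0749. Over probe sets higher in ES, Oct4, Sox2 and Klf4 lay at -0.0218, -0.0184 and -0.0306, within the -0.0628 to 0.0672 of the MEF arrays. Over those higher in MEF they lay at 0.029, 0.0644 and 0.06997, where the MEF arrays lay at -0.0203 to 0.0316. An effect of Oct4, Sox2 or Klf4 was thus not told apart from the state of the uninduced array. At least 2-fold higher were 2219 probe sets with Oct4, 2813 with Sox2, 2724 with Klf4 and 1830 with c-Myc. At least 2-fold lower were 1728, 2471, 2578 and 1671. Between replicate arrays of a line the corresponding counts went from 35 and 50 (1A2) to 964 and 758 (male MEF). The largest single differences were 9.43 for 1436094_at with Oct4, 9.11 for 1418601_at with Sox2, 11.97 for 1417275_at with Klf4 and 6.05 for 1425923_at with c-Myc. Probe set 1424010_at was lower with Klf4 (-9.35) and Oct4 (-5.68).

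1A2 colonies and GFP-sorted 1A2 cells, 1 array each, were compared with the 1A2 line. Colonies lay at positions 0.451 and 0.615 and sorted cells at 0.520 and 0.589. Against the mean of the 1A2 arrays, 2030 probe sets were at least 2-fold higher and 1958 lower in colonies, and 1739 and 1677 in sorted cells. Probe set 1450788_at was 9.06 higher in colonies, and 1420357_s_at differed by -7.38 in sorted cells. The 1A2 arrays belong to the other way of making the values, so these differences cannot be told apart from it.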

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

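The tests of noisy hybridisations, of the scan batch, of the Klf4 hypothesis and of RNA quality were chosen after the results they bear on had been seen, while the tests of mixing and of other splits of the samples were written before. For 20 combinations of a measure and a group of 4 samples, the gap between the highest or lowest sample and the nearest other was set against the range of the group. It was too wide in 3 combinations, for 2 samples. Chance gives about 1 in 20 where combinations are independent, but these share samples, and 2 of the 3 are positions of the same ES array.

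The array of v6.5 ES replicate 1 lay closer to MEF than the other ES arrays. Its position was 0.929 over probe sets higher in ES cells, where the other ES arrays lay at 1.02 to 1.03, and 0.831 over probe sets higher in MEF, where they lay at 1.04 to 1.07. Fibroblast RNA mixed into the sample would raise all MEF transcripts by the same share, and over 487 probe sets the share of MEF RNA had a median of 10.8%, with the upper quartile 2.70 times the lower, which lies between the bounds set in advance and leaves mixing open. Degraded RNA would raise the 3' over 5' signal of the beta-actin controls, which at 1.29 lay below the 1.36 to 1.54 of the other ES arrays and above the 1.11 to 1.19 of MEF, so the value gives no sign of degraded RNA, but it lay below by less than the range of the others and does not settle RNA quality. The design names no difference between this array and the other of its line, so no biological explanation was tested.

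Oct4 and Sox2 at ES-bound promoters were weaker in piPS than in iPS cells, and Sox2 iPS hybridisation 4 stood far from the others, with 3257 promoters bound against 93 to 177. Poor piPS hybridisations stay an open explanation for Oct4. There the best piPS hybridisation ranked ES-bound promoters less well than the poorest iPS one (area under the curve 0.825 and 0.925, a difference of -0.1003). Poor hybridisations would also give this. For Sox2 the best piPS hybridisation reached the poorest iPS one (0.816 and 0.811, a difference of 0.00479). That met the rule set for poor hybridisations as the cause, so they may account for the Sox2 difference. Scan batch stays open for both factors: within 1 batch ES cells shared more of their 1000 highest-scoring promoters with iPS than with piPS cells, by 32.4 points for Oct4 and 34.7 points for Sox2, but the batch held a single piPS hybridisation for each, for Sox2 the poorer one (area 0.582). The state of the piPS cells, the biological difference that the design names, stays open for both factors and was not tested apart from the hybridisations.

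For each expression contrast between groups of at least 3 arrays, the arrays were divided into groups of the same sizes in all 35 ways, the real one included. In each contrast 1 of 35 splits, the real one, gave as many calls, so chance can be excluded among arrays taken as independent. The arrays are repeats of 2 lines per group, and 2 lines against 2 allow no exact p below 0.333, so chance among lines is not excluded. ES against MEF gave 11453 calls where the highest other split gave 1, iPS against ES 1751 and 5, piPS against MEF 7370 and 20, piPS against ES 7308 and 58, and piPS against iPS 6238 and 4. For c-Myc promoter scores of iPS against ES cells all 10 of 10 splits gave as many calls, the real value and the highest other both being 0. In the real one 96 promoters had an unadjusted limma p under 0.05. That count was 5056 without iPS replicate 3 and 3533 with scan batch as a random block. Besides, 10 splits are too few for a share under 0.05.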

How the results depend on the processing

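Each result was recomputed under each alternative, and those with scan batch, equal SD, without noisy hybridisations, with the authors' bound regions, or without v6.5 ES replicate 1 as an end were chosen after the data had been seen. Of the 616 values of the expression counts 595 stayed within 1.5 times the reported count and 21 moved. Leaving out single arrays or lines gave 420 of the values that stayed and 12 of those that moved. Many of these runs left out arrays in neither group of the contrast, so the share that stayed overstates the stability. Of 121 values for bound promoters 49 moved, of 145 for promoters called by limma 79, and of 72 values for single arrays 11, all of these counts. Of 30 positions 19 moved by more than the SD between the arrays of a group, a narrower bound. Of 77 values for shared binding 3 reversed and 74 kept direction and call. Of 16 for the histone marks 2 reversed. Except where stated, the cause was not tested. What signal over background limits was not tested. Single hybridisations of 1 sample differed widely, as the 2 for Sox2 in piPS cells, with 1 and 1505 bound promoters, and 3 of 33 were noisy.

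For expression, averaging the arrays of a line gave 147 probe sets higher and 128 lower in iPS against ES cells, with fewer samples. Without a minimum fold the counts were 1423 and 1495 for iPS against ES, 6760 higher for piPS against MEF, 5775 and 5789 for piPS against ES, and 4984 and 4685 for piPS against iPS, since more probe sets then qualify. Leaving out single arrays or lines, the lowest and highest counts of higher and of lower probe sets were 257 to 979 and 229 to 1408 for iPS against ES, 2357 to 3891 and 2827 to 4167 for piPS against ES, 1714 to 3393 and 2276 to 3261 for piPS against iPS, 2881 to 4207 and 3068 to 3951 for piPS against MEF, 5171 to 6340 and 5049 to 5694 for ES against MEF, 2981 to 4002 and 3353 to 4222 for OCK against MEF, 4265 to 5362 and 4956 to 6023 for OCK against ES, and 1492 to 2665 and 1912 to 3365 for OCK against piPS. The fewest calls came without line 1D4 for iPS against ES (257 and 229), and without 1A2 for higher probe sets in piPS against ES (2357) and iPS (1714) and for OCK against piPS (1492 and 1912).

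The replicate numbers of the labels do not pair the arrays. Across 21 pairs among the 7 lines with 2 arrays, the difference between the arrays numbered 1 and 2 correlated between lines at -0.103 to 0.0707, with 0 pairs over 0.1. With the number as a replicate block the counts were 6083 and 5650 for ES against MEF, 752 and 953 for iPS against ES, 3954 and 3954 for piPS against MEF, 3670 and 3848 for piPS against ES, and 3111 and 3059 for piPS against iPS.

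Positions over probe sets higher in ES cells were 0.824 (iPS), 0.294 (OCK) and 0.479 (piPS) as limited means. With classes called at 4-fold they were 0.908, 0.249 and 0.438, and over probe sets higher in MEF 0.530 for OCK and 0.698 for piPS. With classes from v6.5 and male MEF and ends from E14 and female MEF they were 0.930, 0.258 and 0.458, and 0.472 and 0.635 over those higher in MEF. Without v6.5 ES replicate 1 as an end they were 0.861 (iPS), 0.260 (OCK) and 0.482 (piPS), and 0.831, 0.412 and 0.541 over those higher in MEF. For single arrays above the 60th percentile, with fewer probe sets, counts of 2-fold higher and lower were 1477 and 1113 for Oct4, 1812 and 1701 for Klf4, 1070 and 991 for c-Myc, 1251 and 1163 for colonies and 990 and 961 for sorted cells, and 1619 lower for Sox2.

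The number of bound promoters followed the threshold. At a score of at least 1 it was 1710 for c-Myc in ES and 3455 in piPS, 1944 and 1622 for Klf4 in ES and piPS, 607, 1239 and 368 for Oct4 in ES, iPS and piPS, 263, 341 and 61 for Sox2, 1482 for Nanog, 8601 for H3K4me3 and 4410 for H3K27me3. With mirrored scores at 1 percent it was 2603 for c-Myc in iPS and 908 in piPS, 503 for Klf4 in piPS, 289 and 2490 for Oct4 in ES and iPS, 608, 917 and 41 for Sox2 in ES, iPS and piPS, 1506 for H3K4me3 and 8 for H3K27me3. With normexp it was 1481 and 500 for c-Myc in iPS and piPS, 1764 for Klf4 in piPS, 4303 for Nanog, 387 and 6 for Oct4 in ES and piPS, 885 and 620 for Sox2 in iPS and piPS, 1 for H3K4me3 and 0 for H3K27me3. With 5 probes it was 440 for H3K27me3 and 186 for Sox2 in piPS. With equal SD it was 1063 for c-Myc, 5 for Oct4 and 286 for Sox2 in piPS, and without noisy hybridisations 6 for Oct4 in piPS. Leaving out single hybridisations gave 5161 to 6143 for c-Myc in ES, 3035 to 5570 for c-Myc in iPS, 4822 to 7565 and 4840 to 5785 for Klf4 in ES and iPS, 4422 to 5135 for Nanog, 2858 to 3191 for Oct4 in iPS, 159 to 2023 for c-Myc in piPS, 549 to 3289 for Klf4 in piPS, 467 to 1882 for Oct4 in ES, 0 to 6 for Oct4 in piPS, 243 to 3872 for Sox2 in ES, 1003 to 2312 for Sox2 in iPS and 1 to 1505 for Sox2 in piPS.

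The sizes of the shares moved where their direction held, as for Klf4 in piPS cells (10.2% with mirrored scores at 1 percent, 20.1% with normexp). Shared binding reversed for c-Myc among the 1000 highest-scoring promoters (-6.4 points), within 1 scan batch among the 1000 highest (-13.5) and by the authors' bound regions in every hybridisation (-8.47), the last because the noisy iPS hybridisation has 0 such regions. Leaving out hybridisations, the iPS minus piPS difference stayed within 74.2 to 95.7 points for Oct4, 18.5 to 64.2 for Sox2, 11.4 to 72.7 for Klf4 and 8.13 to 51.6 for c-Myc. The difference in H3K4me3 share between promoters bound or not bound in piPS reversed with normexp, -0.0066 points for Klf4 and -0.0061 for c-Myc, where 1 promoter carried the mark.

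Promoters called by limma depended on the processing. For iPS against ES, piPS against ES and piPS against iPS in that order, normexp gave 98, 316 and 1934 for Oct4 and 32, 2462 (1202 higher, 1260 lower) and 3709 for Klf4. It gave 2 for Sox2 in iPS against ES and 66 in piPS against iPS, and 1 for c-Myc in piPS against ES. With 5 probes, Oct4 had 4 in piPS against ES and 98 in piPS against iPS, and Klf4 had 239 in iPS against ES and 86 in piPS against ES. With equal SD, Oct4 had 265 in piPS against ES and 668 in piPS against iPS, Sox2 3, 64 and 55, Klf4 0, 158 and 30, and c-Myc 194 in piPS against ES (3 higher, 191 lower). Without noisy hybridisations, Oct4 had 14 and 248. With scan batch as a random block, Oct4 had 778 in piPS against iPS, Sox2 3 and 8 in iPS and piPS against ES, and Klf4 0, 13 and 5251. A fixed block absorbs the piPS hybridisation of each factor that is alone in its batch, and compares a single remaining one with iPS. Its counts carry no spread between piPS hybridisations and are listed only as an alternative. A random block can lean on that same comparison. As a fixed block the piPS against iPS counts were 463 for Oct4, 67 for Sox2 and 3888 for Klf4. Leaving out hybridisations gave 0 to 3523 and 0 to 3251 for Oct4 in piPS against ES and iPS, 0 to 490, 2 to 882 and 20 to 334 for Sox2 in that order, and 0 to 23, 0 to 114 and 9 to 1174 for Klf4. For Oct4 in iPS against ES and for c-Myc in each of the 3 contrasts every such run gave 0 by limma, and with all c-Myc hybridisations 96, 111 and 90 promoters had an unadjusted limma p under 0.05. The widest Oct4 counts came without piPS hybridisation 1, which leaves the noisy one (3523 and 3251), and without piPS hybridisation 2 they were 14 and 248. A lone hybridisation is assumed to vary like the other groups. The lowest bound counts came without hybridisation 1 for c-Myc piPS (159) and Oct4 ES (467), and without hybridisation 2 for Klf4 piPS (549), Sox2 ES (243) and Sox2 piPS (1).

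Not run were the set tests on expression, the mean over probe sets of a gene, the check of sex-linked genes, binding against expression and the platform value tables. The fit of only OCK and piPS arrays could not be estimated.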

Other observations

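The factor given for each of the following gene groups was chosen after its values were seen. Neural genes were bound by Sox2 at 4 of 18 promoters in ES, 10 in iPS and 0 in piPS cells, and their median Sox2 percentile was 62.8 in ES, 87.7 in iPS and 57.0 in piPS cells (higher in iPS than in piPS at 16 of 18, adjusted exact sign p = 0.0178). Developmental regulators were bound by Sox2 at 3, 14 and 0 of 34 promoters. Genes of chromatin and DNA methylation were bound by Oct4 at 12, 18 and 0 of 26 promoters. All 12 of those bound in ES cells were bound in iPS cells (adjusted exact McNemar p = 0.00474). With 2 promoters bound by Oct4 in piPS cells in all, that test could hardly have come out otherwise. Imprinted genes were bound by Klf4 at 16, 17 and 8 of 20 promoters. Genes of the p53 pathway and senescence were bound by c-Myc at all 14 promoters in ES cells, at 6 in iPS and 7 in piPS cells. Germline genes were bound by c-Myc at 9, 4 and 0 of 21 promoters and carried H3K4me3 at 2. Interferon response genes were bound by Klf4 at 10, 8 and 4 of 22 promoters, and blood and endothelial genes at 6, 6 and 3 of 17. Epithelial genes were bound by Klf4 at 18, 19 and 9 of 22 promoters (adjusted exact McNemar p = 0.0443 for those bound in ES), and by c-Myc at 13, 6 and 1. The epithelial share kept by Klf4 in piPS cells (50% against 53.1% of other promoters, adjusted Fisher p = 1) and the chromatin share kept by Oct4 (0% against 0.0956%, adjusted Fisher p = 1) were not called different from other promoters.

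At the promoter of Myc, limma called a change for Sox2 and none for Oct4 or Klf4. Its Oct4 score was 0.88 ± 0.17 (SD, n = 2) in ES, 2.37 ± 1.64 (n = 2) in iPS and 1.12 ± 0.36 (n = 2) in piPS cells, and its Sox2 score was 0.43 ± 0.23 (n = 2), 0.70 ± 0.23 (n = 4) and 1.96 ± 0.67 (n = 2). In piPS cells the window with the highest score for both factors was the same (chromosome 15, 61817118 to 61817537), and Myc ranked 3 among all promoters for Sox2. Klf4 was bound at Myc in all of the cell types, at 1.31 ± 0.07 (n = 3), 1.53 ± 0.18 (n = 2) and 1.16 ± 0.26 (n = 2). The cause of the Sox2 signal was not tested.

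Some Sox2 promoters of ES cells rested on 1 of 2 hybridisations. Vmac had 1.88 ± 2.46 (SD, n = 2) in ES cells and Uimc1 1.92 ± 2.47, with 0.22 ± 0.06 (n = 4) and 0.21 ± 0.16 in iPS cells. The uninduced MEF array differed from the mean of the MEF arrays by at least 2-fold at 2247 probe sets higher and 2386 lower, of 18413 above the median, which spans the difference in how the values were made.

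A hypothesis, whose test was chosen after the shares had been seen, was that Klf4 was lost in piPS cells where Oct4 or Sox2 had also bound in ES cells. With both piPS hybridisations together the values did not show that loss. Klf4 was kept at 63.8% of promoters with Oct4 or Sox2 and at 47.2% of those without, and within 10 bins of the Klf4 score in ES cells the Mantel-Haenszel odds ratio was 1.13 (95% interval 1.006 to 1.26), where the hypothesis needs a ratio below 1. In iPS cells the shares were 88.4% and 75.3% and the ratio 1.20 (1.02 to 1.40). Klf4 was kept in piPS cells more often where c-Myc had also bound in ES cells, at 60.4% against 40.01% (ratio 1.73, 1.55 to 1.92). These intervals are over promoters and contain no spread between samples. The share of Klf4 promoters kept in piPS cells fell from 53.1% to 7.30% without piPS replicate 2. The ratios were not repeated without it, so the values do not settle the hypothesis.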
